A study of Mus musculus with 8 samples.

How the data were processed

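Retinas of mouse pups were collected on postnatal day 7, after intraperitoneal tamoxifen (1 mg per ml) from day 1 to day 3, and polyadenylated RNA was sequenced as 2 x 150 base reads, per the labels. The 8 libraries formed 4 groups of 2: controls without the 2B allele (floxed alleles, no Cre), controls with the 2B allele (1 floxed and 1 2B allele, no Cre), Vhl null (floxed alleles with Cre) and 2B mutant (floxed and 2B alleles with Cre, by the series' design text). No group carried Cre without a floxed allele, so effects of Cre itself are part of each Cre comparison. The deposited files hold raw counts per gene, 1 library per file, made by the authors with STAR, SAMtools and featureCounts on GRCm38 per the submitters' processing notes. Tool versions, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The values were checked to be whole numbers with a different total in each file.

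Each file held 51826 genes, of which 51633 were matched to symbols of GENCODE M21 by identifier without version and 193 were not. Total counts per library ran from 11243605 to 15285661, and the Wilson 95% intervals given with shares of counts cover counting error only. Genes were filtered with filterByExpr, which left 19927 of the 36197 genes with any count, and scaled by the trimmed mean of M-values (TMM). The quasi-likelihood test of edgeR 4.0.16 with robust dispersion (R 4.3.3) was fitted to all 4 groups at once, with 4 residual degrees of freedom and a biological coefficient of variation of 0.223. The pooled comparison of 4 Cre-positive with 4 Cre-negative libraries had a fit of its own with 6 residual degrees of freedom (0.239). The main comparisons were Vhl null and 2B mutant, each against its Cre-negative control. The others were 2B mutant against Vhl null, the controls against each other, the difference between the main comparisons and the pooled comparison. P-values were adjusted by Benjamini-Hochberg and genes called at an adjusted p under 0.05. "Adjusted over the list alone" means the same adjustment within the members of 1 list.

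Groups, comparisons, the 13 named genes, 30 gene lists and most alternatives were chosen before the data were examined. The lists covered VHL-HIF machinery, hypoxia, glycolysis, Notch, vessel, neuronal, glial, immune, proliferation, lens, blood, muscle, mitochondrial, stress and sex-linked genes. They held 669 memberships, 6 matched through synonyms and 3 without a gene in the files. Lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, an estimated correlation as an alternative, and fry, whose counts are of its directional test unless its mixed test is named. A list's level in a library was the mean log2 CPM of its members relative to their mean over the libraries. Genes were to be named where they belonged to the 13, were among the 10 largest increases or decreases past the threshold with a mean CPM of at least 1, or defined a list. Since no gene passed in edgeR, list members were taken as examples. Lists of adipocyte and of corneal and skin epithelium markers were added after the values were seen and tested apart. The level of Vhl was tested by exact permutation of 70 arrangements.

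Alternatives were DESeq2 size factors (RLE) in edgeR, no low-count filter, a filter of CPM at least 1 in at least 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, the sample number prefix as a term, Xist as a covariate for sex, the compared libraries alone, a fold change of at least 1.5, the 2B allele as a term, the mean of both Cre contrasts, and leaving out each of the 8 libraries in turn. Added after the data were seen were the crystallin percent as a covariate, removal of crystallin, haemoglobin, mitochondrial and ribosomal RNA counts, leaving out the 3 libraries with prefix 11, and an unadjusted p under 0.05 in both main comparisons. The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the null comparison edgeR recovered 15% and 75% of them with 12 false calls, DESeq2 20% and 75% with 12, and limma-voom 12% and 70% with 11. For the pooled comparison the shares were 48% and 93% with 11 false calls, 54% and 93% with 24, and 48% and 92% with 7. Simulated libraries on the same side of it shared their mean for each gene, without differences by prefix or 2B allele. These shares can therefore be too high for the real libraries. Of 5 simulated lists shifted by 0.5, camera called 5 in both designs with the preset correlation, and 1 (null) and 5 (pooled) with an estimated correlation. The simulated genes varied independently of each other. The trial therefore favours the preset correlation and does not show how often it calls lists of correlated genes falsely. In the real data, splits of the 8 libraries into 4 and 4 other than that by Cre gave a median of 9 lists called with it. A call with the preset correlation alone is thus weak evidence, however small its p-value. Replicates varied more than counting error, with a chi-square per gene of 7.80, 35.5, 61.0 and 47.6 in the controls without and with the 2B allele, the null and the mutant, against 1 by chance.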

Results

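Messenger RNA was sequenced from 8 mouse retinas taken on postnatal day 7, after tamoxifen had been given from day 1 to day 3 to switch on a Cre recombinase expressed in most tissues. The libraries came from 4 genotypes, with 2 each. The controls lacked Cre and had either both Vhl alleles floxed or 1 floxed allele beside a germline 2B allele. Type 2B is a class of human VHL mutation tied to pheochromocytoma with a high risk of renal cancer. The Vhl null had floxed alleles with Cre. The 2B mutant had Cre with a 2B and a floxed allele by the series' design text, whereas its sample titles read 2B with lox-lox, and the design text was followed. Total counts were 13622053 and 11860234 in the controls without the 2B allele, 14485531 and 15285661 in the controls with it, 12302705 and 12072900 in the Vhl null, and 11243605 and 12537540 in the 2B mutant. Levels are given in CPM, the usual unit of counts scaled to library size, as mean ± SD over the libraries of a group. The labels do not say that the replicates came from separate animals. In the control without the 2B allele, the Vhl null and the 2B mutant, only 1 replicate had counts of the Y-linked gene Eif2s3y (given below). Those replicates thus differed in sex and came from separate animals, so their spread is not technical alone. Neither control with the 2B allele had such counts, which leaves this open there. The p-values measure the spread between these samples. Sample numbers in the labels begin with 11 (both controls without the 2B allele and replicate 1 with it), 12 (replicate 2 with the 2B allele, Vhl null replicate 1 and both 2B mutants) or 13 (Vhl null replicate 2). The meaning of this prefix is not given in the sources used here, and a single Cre-negative library shares a prefix with any Cre-positive one.

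The targeted gene was examined first. Vhl (ENSMUSG00000033933; chromosome 6, 113623959 to 113631633, GRCm38, exons free of overlap with other genes) encodes the substrate receptor of the ubiquitin ligase that marks the alpha subunits of hypoxia-inducible factors for degradation. Its level was 39.9 and 40.2 CPM in the controls without the 2B allele, 42.3 and 39.2 CPM in those with it, 30.3 and 20.1 CPM in the Vhl null, and 27.3 and 36.1 CPM in the 2B mutant. Every Cre-positive library thus lay below every Cre-negative one, at 28.4 ± 6.66 CPM against 40.4 ± 1.34 CPM, or 70.3% of the control mean (two-sided exact permutation test, p = 0.0286, the smallest p that 4 against 4 allows, n = 4 per side). This test was added after the values were seen. Which exons the floxed allele loses is not given in the sources used here, so the remaining counts are no measure of the share of cells that recombined.

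Comparing the Vhl null with its Cre-negative control asks what loss of both alleles does to the retina. Genes known to respond to hypoxia were higher in the null: 41 of the 47 measured members of that list had a log2 fold change above 0, with a list median of 0.44. Stc2, a secreted stanniocalcin, was at 11.3 ± 1.39 CPM in the null against 2.28 ± 0.0210 CPM in the control, a 4.94-fold difference. Adm, which encodes the vasodilator peptide adrenomedullin, was at 6.12 ± 1.92 CPM against 1.27 ± 0.122 CPM, a 4.76-fold difference. Proliferation genes lay lower, with 29 of 30 members below 0 and a list median of -0.66. So did markers of skeletal muscle, a tissue outside the retina, with a list median of -1.02. The genes picked out from the lists here and below were chosen after their values were seen. In all, 17 hypoxia genes rose and 1 fell when adjusted over the list alone.

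Among the 13 genes named before the data were examined, 4 HIF targets and Vhl itself passed 0.05 adjusted over the list alone. Egln3, the prolyl hydroxylase that marks HIF subunits, rose 2.37-fold (log2 fold change 1.25 ± 0.31 SE, adjusted p = 0.0289). Slc2a1, the glucose transporter GLUT1, rose 1.81-fold (0.86 ± 0.27 SE) and Vegfa, the vascular growth factor, 1.74-fold (0.80 ± 0.26 SE). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose 1.43-fold (0.52 ± 0.18 SE). Slc2a1, Vegfa and Pdk1 each had an adjusted p of 0.0435. Vhl decreased by 0.67 (± 0.24 SE) with the same adjusted p. Without null replicate 1 or 2 its value was -0.99 or -0.40. Both controls of this comparison have prefix 11 and the null libraries prefix 12 or 13. Replicate 2 of the control with the 2B allele, of prefix 12, had 24.22 CPM of Egln3 without Cre. The other Cre-negative libraries had 11.35 to 13.23 CPM. The rises of the 4 HIF targets therefore cannot be told apart from the prefix. Hif1a (0.18), Epas1 (0.25), Notch1 (0.20), Dll4 (0.02), Hey1 (0.19), Hes1 (-0.26), Pdgfrb (-0.38) and Pecam1 (-0.18) did not pass. With 1 null library left out, Notch1 ranged from 0.0059 to 0.39, Pecam1 from -0.35 to -0.014, Hes1 from -0.38 to -0.13, Hey1 from 0.094 to 0.31, Epas1 from -0.085 to 0.55 and Dll4 from -0.28 to 0.29. Exons of Slc2a1 overlap the antisense gene Gm12868, and those of Notch1, Dll4 and Hif1a overlap other genes. Their counts are less certain where the counting did not use strand. Hif1a also overlaps Gm49321 on its own strand, which use of strand would not resolve. In GRCm38, Vegfa lies on chromosome 17 (46016993 to 46032369), Slc2a1 on chromosome 4 (119108711 to 119137983), Egln3 on chromosome 12 (54178981 to 54203860), Pdk1 on chromosome 2 (71873224 to 71903858), Stc2 on chromosome 11 (31357307 to 31370074) and Adm on chromosome 7 (110627661 to 110629820).

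**Figure D1:**
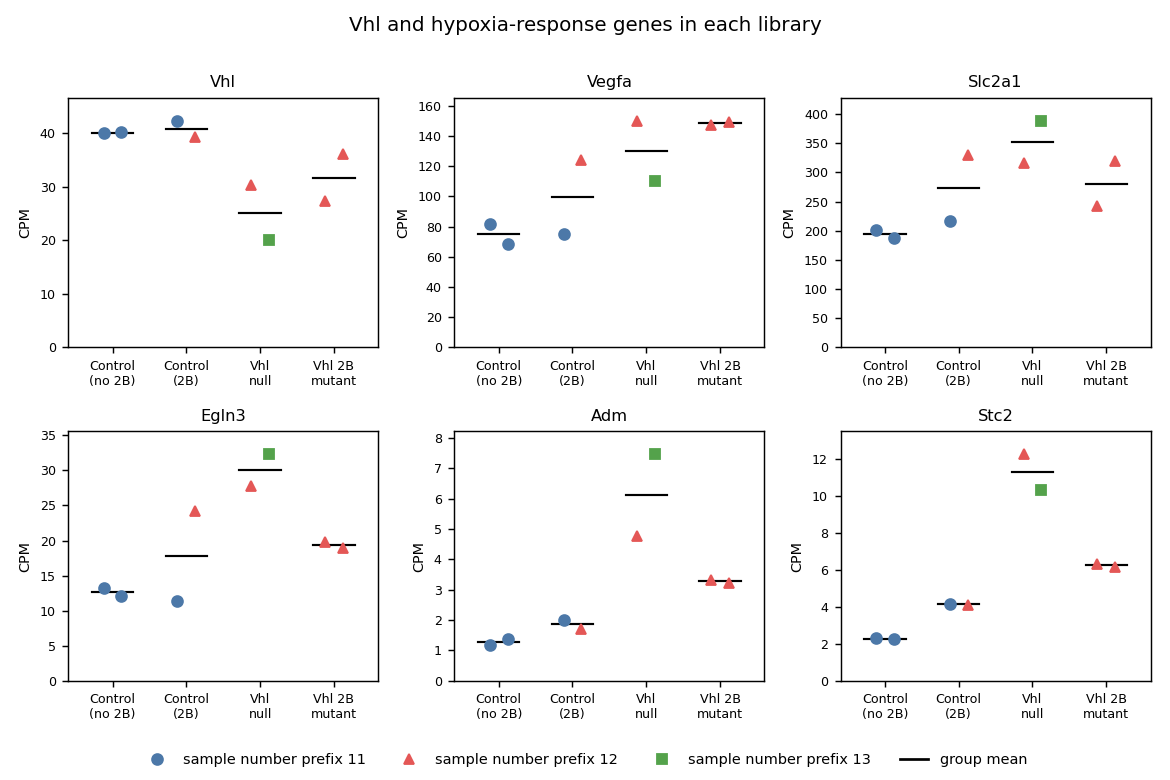
Normalised level in CPM (counts scaled to library size, vertical axis) of Vhl, Vegfa, Slc2a1, Egln3, Adm and Stc2 in each of the 8 libraries by genotype (horizontal axis), with symbols for the sample number prefix and a black line at the group mean. Vhl lies at 39.2 CPM or above in the Cre-negative libraries and at 36.1 CPM or below in the Cre-positive ones, and for Vegfa, Slc2a1 and Egln3 the control with prefix 12 lies nearer to the Cre-positive libraries than the other controls do.

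Across all 19927 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05 between null and control, with 2924 genes at an unadjusted p under 0.05 against 996 by chance. DESeq2 called 100 genes, 47 up and 53 down, and limma-voom 0. The unadjusted count was 1425 or 1520 without either control library, 1728 with the prefix in the model and 4362 without null replicate 2. The smallest adjusted p in edgeR was 0.115, and Stc2, Ier3, Mylpf and Myl1 were among the genes that had it. DESeq2's calls included 5 of the hypoxia list (Stc2, Adm, Bnip3, Egln1 and Egln3), 2 of glycolysis, 3 of the rods and 6 of muscle. On simulated counts for this comparison edgeR recovered 15% of genes changed 2-fold and 75% of those changed 4-fold.

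The gene lists were tested against all other genes with camera. The hypoxia list was called at an adjusted p of 4.12e-11 with the preset correlation (adjusted p = 0.171 with an estimated correlation). Besides those above, the mitophagy receptor Bnip3 (0.97 ± 0.24 SE), the hydroxylase Egln1 (0.96 ± 0.23 SE), the carbonic anhydrase Car12 (0.93 ± 0.22 SE), Ero1l (0.84 ± 0.24 SE) and Ak4 (0.81 ± 0.22 SE) rose, and Cox4i2, a cytochrome oxidase subunit, fell by 0.65 (± 0.23 SE), adjusted over the list alone. Without null replicate 2 the Egln1 value was 0.60. The list's mean deviation was 0.236 and 0.278 in the null libraries and between -0.252 and 0.121 in the other 6. Glycolysis and glucose uptake was higher (median 0.32, 22 of 27 members above 0, adjusted p = 3.85e-05; adjusted p = 0.522 with an estimated correlation), and 2 members rose adjusted over the list alone: hexokinase Hk2 (1.27 ± 0.24 SE) and the lactate exporter Slc16a3 (1.00 ± 0.19 SE). The median of the hypoxia list was 0.29 with the sample number prefix in the model (adjusted p = 0.000756; adjusted p = 0.818 with an estimated correlation). With that term the estimate rests on the 1 Cre-negative library of prefix 12, and null replicate 2, alone with prefix 13, does not enter it.

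Neuronal and proliferation markers also shifted. The rod list was higher (median 0.48, 21 of 25 above 0, adjusted p = 0.000164; adjusted p = 0.561 with an estimated correlation), and the phosphodiesterase subunit Pde6b (1.11 ± 0.27 SE), the nuclear receptor Esrrb (1.44 ± 0.37 SE) and the exchanger Slc24a1 (0.97 ± 0.27 SE) rose adjusted over the list alone. Retinal ganglion cell (median 0.48, 20 of 21 above 0, adjusted p = 0.00629) and amacrine and horizontal cell lists (0.37, adjusted p = 0.0214) were called too, each with adjusted p = 0.561 with an estimated correlation. The vesicular glutamate transporter Slc17a6 rose within the first (0.79 ± 0.20 SE). Cell cycle and proliferation was lower (adjusted p = 3.52e-09; adjusted p = 0.522 with an estimated correlation), and 9 members fell adjusted over the list alone. Among them thymidylate synthase Tyms fell by 1.52 (± 0.30 SE), the mitotic kinase Cdk1 by 1.09 (± 0.35 SE), topoisomerase Top2a by 1.07 (± 0.31 SE) and the replication clamp Pcna by 0.91 (± 0.24 SE). Nuclear-encoded mitochondrial respiration was lower (median -0.41, 29 of 35 below 0, adjusted p = 7.28e-05; adjusted p = 0.561 with an estimated correlation). With the prefix in the model the calls of rods (median 0.29, adjusted p = 0.0731), ganglion cells (0.20, adjusted p = 0.318) and mitochondrial respiration (-0.18, adjusted p = 0.391) ended. Without null replicate 1 the medians of rods and mitochondrial respiration were 0.19 and -0.21. Without Vhl null replicate 2 the ganglion cell median was 0.02 and its call ended, as it did without control replicate 1 (0.26). The amacrine and horizontal call ended without control replicate 1 or null replicate 1.

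Transcripts typical of tissues outside the retina were counted in every library. Crystallins, the lens proteins, took 25.2 ± 0.356% of counts in the controls without the 2B allele, 24.2 ± 1.80% in those with it, 26.1 ± 6.90% in the Vhl null and 18.9 ± 1.43% in the 2B mutant. All 20 muscle genes were lower in the null (adjusted p = 2.58e-17; adjusted p = 0.237 with an estimated correlation), and 13 fell adjusted over the list alone, with the fast light chains Myl1 and Mylpf falling by 1.84 (± 0.28 SE) and 1.73 (± 0.25 SE). Muscle genes made up 0.161 ± 0.0264% of counts in that control and 0.0676 ± 0.0158% in the null. Of 13 adipocyte markers, a list chosen after the values were seen, 11 were lower in the null (median -2.33, adjusted p = 1.73e-09; adjusted p = 0.0918 with an estimated correlation), while 8 of 12 corneal and skin epithelium markers, also added, were lower (median -0.13, upward test, adjusted p = 0.832).

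In the 2B mutant, compared with the control that carries the 2B allele without Cre, hypoxia genes moved less. The list median was 0.12 with 29 of 47 members above 0 (adjusted p = 0.0441; adjusted p = 0.669 with an estimated correlation), and 0 members passed adjusted over the list alone. Vegfa was at 148 ± 1.69 CPM in the mutant and 99.7 ± 34.8 CPM in the control (log2 fold change 0.57 ± 0.26 SE). Proliferation genes were lower, with 25 of 30 below 0 and a median of -0.51. Rod genes were higher, with 20 of 25 above 0 and a median of 0.35, and Slc24a1 rose within that list (1.28 ± 0.26 SE, adjusted p = 0.0123 over the list alone).

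Of the 13 genes named beforehand, 0 passed adjusted over the list alone in edgeR, with Vegfa, Epas1 (0.51 ± 0.25 SE) and Pdk1 (0.34 ± 0.18 SE) nearest, each at an adjusted p of 0.362. Vhl was at -0.36 (± 0.23 SE), Hes1 at -0.34, Dll4 at -0.33, Notch1 at -0.30, Pdgfrb at -0.18, Slc2a1 at 0.04, Egln3 at 0.12, Hey1 at 0.14, Pecam1 at 0.20 and Hif1a at 0.20. With 1 mutant library left out, Vhl ranged from -0.58 to -0.18, Dll4 from -0.79 to -0.0036 and Notch1 from -0.53 to -0.11. With any 1 library left out, Hif1a ranged from 0.075 to 0.30, Pecam1 from 0.077 to 0.31, Hey1 from 0.030 to 0.22 and Hes1 from -0.50 to -0.21. Without replicate 1 or 2 of the control, Vegfa was at 0.25 or 0.94 and Epas1 at 0.27 or 0.78. The estimates of Slc2a1 and Egln3 turned to -0.23 and -0.32 with the prefix in the model. With that term the mutants are in effect compared with replicate 2 of their control alone. Leaving out replicate 1 of that control gave -0.23 and -0.32 too. In the control with the 2B allele, replicate 2 had 24.2 CPM of Egln3 where replicate 1 had 11.3 CPM. Over all genes edgeR called 0 with 1309 at an unadjusted p under 0.05, DESeq2 called 35 (9 up, 26 down) and limma-voom 0. That unadjusted count fell to 758 without mutant replicate 1, 818 without control replicate 1 and 459 without the libraries of prefix 11. It rose to 2379 or 2392 without either null library.

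Of the lists, cell cycle and proliferation (adjusted p = 7.93e-08), lens, RPE and other eye tissue (median -0.50, adjusted p = 2.89e-06), extraocular muscle (-0.43, adjusted p = 0.000421), microglia and macrophage (-0.38, adjusted p = 0.0005), erythroid (-0.58, adjusted p = 0.0235), retinal progenitor (-0.29, adjusted p = 0.0199) and nuclear-encoded mitochondrial respiration (-0.15, adjusted p = 0.0143) were lower. Mitochondrially encoded transcripts (0.76, adjusted p = 0.00289), rods (adjusted p = 0.00541), bipolar cells (0.35, adjusted p = 0.0105) and ganglion cells (0.20, adjusted p = 0.0310) were higher. Each of these 11 lists had an adjusted p = 0.669 with an estimated correlation. Cell cycle kept its call in every refit that left out a library or added the prefix, sex or crystallin share, with a median of -0.26 without mutant replicate 2. The hypoxia call ended with Xist as a covariate (0.09, adjusted p = 0.0912) and when any 1 of 5 libraries was left out, with medians of 0.07 without mutant replicate 1 and 0.20 without replicate 1 of its control. The ganglion cell median was 0.04 without replicate 2 of its control (adjusted p = 0.299), and that call also ended with Xist (0.14) or without mutant replicate 2 (0.13). The rod, progenitor, hypoxia and mitochondrial respiration calls ended with the prefix in the model (medians 0.09, 0.02, 0.20 and 0.01), and without mutant replicate 1 the mitochondrially encoded median turned to -0.23. That call also ended without replicate 2 of the control (0.22), as did those of lens (-0.34), microglia (-0.17) and bipolar cells (0.36) without mutant replicate 2 and those of rods (0.09) and progenitors (0.02) without replicate 1 of the control. The calls of lens (-0.17), microglia (-0.06), bipolar cells (0.00), rods (0.17), progenitors (-0.06), mitochondrial respiration (-0.15) and erythroid genes (0.07) ended with the crystallin share as a covariate. The erythroid call also ended without mutant replicate 1 (-0.30, adjusted p = 0.241) and without either control library (-0.51 and -0.60). Among muscle genes none passed adjusted over the list alone, and that call ended without mutant replicate 1 (-0.21). Adipocyte markers were lower here as well (median -1.12, 9 of 13 below 0, adjusted p = 8.46e-06; adjusted p = 0.205 with an estimated correlation).

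Setting the 2B mutant against the Vhl null, both with Cre, asks whether a remaining 2B allele acts differently from no allele. Hypoxia genes were lower in the 2B mutant, with 35 of 47 below 0 and a median of -0.20 (adjusted p = 0.000579; adjusted p = 0.467 with an estimated correlation), though 0 passed adjusted over the list alone. Stc2 was at 6.24 ± 0.0963 CPM in the mutant against 11.3 ± 1.39 CPM in the null (-0.86 ± 0.26 SE) and Adm at 3.28 ± 0.0772 CPM against 6.12 ± 1.92 CPM (-0.89 ± 0.34 SE), with an adjusted p of 0.963 for both over all genes. Blood genes differed most, with a median of -1.97 (adjusted p = 3.09e-15; adjusted p = 0.467 with an estimated correlation) and 7 of 10 fallen adjusted over the list alone, among them the haemoglobins Hbb-bs (-2.16 ± 0.52 SE) and Hba-a1 (-1.82 ± 0.48 SE). Haemoglobin genes took 0.425% and 1.30% of counts in the null libraries (Wilson 95% intervals 0.421 to 0.429% and 1.30 to 1.31%) and 0.255 ± 0.0688% in the mutant, and without null replicate 2 the list median was -0.76.

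The list of lens, RPE and other eye tissue, called lens for short, was lower in the mutant too (-0.44, adjusted p = 8.12e-11; adjusted p = 0.472 with an estimated correlation). Also lower were microglia (-0.41, adjusted p = 1.97e-08; adjusted p = 0.621 with an estimated correlation) and unfolded protein stress genes (-0.20, adjusted p = 0.0295; adjusted p = 0.467 with an estimated correlation). Mitochondrial respiration (-0.20, adjusted p = 0.000577), immediate early genes (-0.32, adjusted p = 0.0242), bipolar cells (0.19, adjusted p = 0.0263) and muscle (0.13, adjusted p = 0.0263) were called as well, each with adjusted p = 0.693 with an estimated correlation. With the crystallin share as a covariate 3 lists were called, and the hypoxia median was -0.11 (adjusted p = 0.0807). Without null replicate 2 the medians of lens and microglia were -0.19 and -0.07, and without mutant replicate 2 the hypoxia median was -0.12 and its call ended, as did that of microglia. The bipolar and immediate early medians turned to -0.0017 and 0.016 without null replicate 2, and that of muscle to -0.09 without mutant replicate 2, each losing its call. The calls of mitochondrial respiration (-0.12) and unfolded protein stress (-0.17) ended without mutant replicate 2, and the latter's also without null replicate 2 (-0.10, adjusted p = 0.302). Over all genes edgeR called 0, DESeq2 called 23, all lower, and limma-voom 0. In edgeR 673 genes had an unadjusted p under 0.05, fewer than the 996 by chance. The unadjusted count was 359 without null replicate 2 and 1263 without mutant replicate 2. Without null replicate 1 it was 4046, and edgeR called 79. The lone null library left was then taken to vary like the other groups.

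The test of the difference between both Cre effects called 0 genes in edgeR, with 684 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The unadjusted count was 432 without replicate 1 of the control lacking the 2B allele, 1684 without mutant replicate 2 and 2604 without null replicate 1. The hypoxia list was shifted less in the 2B mutant than in the Vhl null (median of the difference -0.37, 39 of 47 below 0, adjusted p = 1.72e-06; adjusted p = 0.486 with an estimated correlation). Its level was -0.148 in the control with the 2B allele of prefix 11 and -0.00388 in that of prefix 12. Part of the difference can therefore come from the prefix. Within prefix 12, where the null has 1 library, the mean deviation of the mutant less that of the null was -0.184. At an unadjusted p under 0.05 the 2 comparisons, which share no library, had 148 genes higher in both against 35.9 by independence and 282 lower in both against 61.2. In both comparisons the Cre-positive libraries have prefix 12 or 13 and the controls wholly (null) or partly (mutant) prefix 11, so the excess can come from the prefix as well as from Cre. Their log2 fold changes had a Pearson r of 0.198 and a Spearman rho of 0.339 across 19927 genes, which are not independent replicates.

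Between both kinds of control, which asks whether a 2B allele acts without recombination, glycolysis (median 0.20, adjusted p = 0.0101) and hypoxia genes (0.24, adjusted p = 0.0262) were higher with the 2B allele. Muscle (-0.45, adjusted p = 0.000157), nuclear-encoded (-0.40, adjusted p = 3.74e-06) and mitochondrially encoded respiration (-0.77, adjusted p = 0.000157) were lower. All 5 lists had an adjusted p = 0.933 with an estimated correlation. The muscle median was -0.28 without replicate 2 of the control lacking the allele, and the nuclear-encoded one -0.27 without replicate 2 of the control with it. Of the added lists, adipocyte markers were lower (-0.45, 12 of 13 below 0, adjusted p = 0.0157) and corneal and skin epithelium markers higher (0.55, 11 of 12 above 0, adjusted p = 0.0137), each with adjusted p = 0.404 with an estimated correlation. Stc2 was at 4.14 ± 0.0387 CPM with the allele and 2.28 ± 0.0210 CPM without it (0.86 ± 0.29 SE), and Hk2 at 13.0 ± 0.412 CPM against 7.89 ± 1.53 CPM (0.72 ± 0.24 SE), with adjusted p of 0.402 and 0.392 over all genes. Without replicate 2 of the control with the 2B allele, the library with prefix 12, the hypoxia median was 0.10 (adjusted p = 0.154) and the mitochondrially encoded median -0.36 (adjusted p = 0.188), and with the prefix in the model these calls ended too (0.10 and -0.37). The glycolysis call ended without replicate 1 of either control (0.16 and 0.23). In edgeR 0 genes passed, with 2141 at an unadjusted p under 0.05, DESeq2 called 21 (9 up, 12 down) and limma-voom 0. The unadjusted count was 1001 or 982 without either control lacking the allele and 851 without replicate 2 of those with it, so its excess over chance ended with 1 library.

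Notch signalling and the vessel wall, which the series' title puts at its centre, showed no called shift in most tests. The RNA came from retinas and not from sorted vessel cells, so a shift confined to vessels could be diluted. On simulated counts for the null comparison edgeR recovered 15% of genes changed 2-fold. A missing call is therefore no sign that vessel cells were unchanged. The list of 32 Notch pathway genes had a median of 0.09 in the null (adjusted p = 0.479), -0.18 in the 2B mutant (adjusted p = 0.100) and -0.06 over both Cre groups (adjusted p = 0.772). Tip cell genes stood at 0.20 in the null (adjusted p = 0.163) and 0.01 in the 2B mutant (adjusted p = 0.621), though Adm rose within the list adjusted over it alone. Pericyte and smooth muscle genes stood at -0.10 (adjusted p = 0.197) and -0.01 (adjusted p = 0.718), arterial genes at 0.11 (adjusted p = 0.754) and -0.17 (adjusted p = 0.621), and vascular basement membrane and collagens at 0.18 (adjusted p = 0.614) and -0.25 (adjusted p = 0.0515). Venous genes had a median of 0.07, a mean of -0.06 and a downward test in the null (adjusted p = 0.953). The endothelial list was lower in the null (-0.38, 24 of 33 below 0, adjusted p = 0.0434; adjusted p = 0.887 with an estimated correlation), with 0 members past adjusted over the list alone, and stood at 0.04 in the 2B mutant (adjusted p = 0.654). That call ended when any 1 of 6 libraries was left out, with a median of -0.14 without control replicate 1 or without null replicate 1.

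The remaining lists were not called in the null. Medians were 0.19 for VHL-HIF machinery (adjusted p = 0.163), -0.11 for cones (adjusted p = 0.953), 0.02 for bipolar cells (adjusted p = 0.680), 0.12 for Mueller glia (adjusted p = 0.255), 0.15 for astrocytes and gliosis (adjusted p = 0.182) and -0.12 for retinal progenitors (adjusted p = 0.479). They were -0.02 for lens and RPE (adjusted p = 0.680), 0.41 for blood (adjusted p = 0.116), -0.37 for mitochondrially encoded transcripts (adjusted p = 0.163), 0.02 for integrated and unfolded protein stress (adjusted p = 0.764), 0.10 for interferon and antigen presentation (adjusted p = 0.163) and -0.03 for apoptosis and p53 (adjusted p = 0.953). Microglia (median 0.01, downward test, adjusted p = 0.754), immediate early (-0.05, upward test, adjusted p = 0.368) and sex-linked genes (-0.10, upward test, adjusted p = 0.953) had a test of the other sign than the median.

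Pooling 4 Cre-positive against 4 Cre-negative libraries gave more power on simulated counts than the null comparison, the only other comparison simulated. Hypoxia genes were higher with Cre (median 0.34, 37 of 47 above 0, adjusted p = 2.79e-08; adjusted p = 0.370 with an estimated correlation), and 10 rose and 1 fell adjusted over the list alone. Ak4, a mitochondrial adenylate kinase, was at 16.7 ± 0.997 CPM against 10.3 ± 0.684 CPM (0.69 ± 0.15 SE), Vldlr, a lipoprotein receptor, at 98.3 ± 6.79 CPM against 64.0 ± 6.83 CPM (0.62 ± 0.13 SE) and Bnip3 at 145 ± 27.2 CPM against 83.5 ± 10.2 CPM (0.79 ± 0.17 SE). Cell cycle genes were lower (-0.58, 29 of 30 below 0, adjusted p = 8.27e-14; adjusted p = 0.345 with an estimated correlation), with 16 fallen adjusted over the list alone, among them Cdc20, an activator of the anaphase-promoting complex (-0.97 ± 0.24 SE). Rod genes were higher (0.41, adjusted p = 3.14e-05; adjusted p = 0.431 with an estimated correlation) and muscle genes lower (-0.68, adjusted p = 6.61e-14; adjusted p = 0.370 with an estimated correlation), with 12 muscle genes fallen adjusted over the list alone.

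Glycolysis (0.15, adjusted p = 0.000667; adjusted p = 0.653 with an estimated correlation), ganglion cells (0.24, adjusted p = 0.000929; adjusted p = 0.551 with an estimated correlation) and amacrine and horizontal cells (0.25, adjusted p = 0.0201; adjusted p = 0.678 with an estimated correlation) were higher. Mitochondrial respiration (-0.29, adjusted p = 0.000131; adjusted p = 0.678 with an estimated correlation), progenitors (-0.17, adjusted p = 0.0480) and lens (-0.21, adjusted p = 0.0201) were lower, the last 2 with an adjusted p = 0.708 with an estimated correlation. Among single genes, chosen after their values were seen, Serpinh1, the collagen chaperone HSP47, was at 160 ± 33.6 CPM with Cre and 303 ± 23.8 CPM without (-0.92 ± 0.18 SE), and Tmem119, a microglial gene, at 6.19 ± 0.749 CPM against 12.0 ± 1.55 CPM (-0.95 ± 0.18 SE). The endoplasmic reticulum gene Sdf2l1 was at 3.25 ± 0.571 CPM against 8.67 ± 2.88 CPM (-1.42 ± 0.27 SE). Without Vhl null replicate 2 the hypoxia median was 0.20. With the prefix in the model it was 0.17 (adjusted p = 0.132), the rod median 0.21 (adjusted p = 0.0866), the muscle median -0.22 (adjusted p = 0.00325) and the cell cycle median -0.50 (adjusted p = 3.75e-06), the last 3 with an adjusted p = 0.772 with an estimated correlation. With it mitochondrial respiration turned to 0.03 and the calls of progenitors (-0.09), glycolysis (0.09) and amacrine and horizontal cells (0.16) ended. The progenitor call ended in 10 refits and turned without the libraries of prefix 11 (0.05), the lens median was -0.09 without mutant replicate 2, and the ganglion cell call ended without Vhl null replicate 2 (0.14). Within the 4 libraries of prefix 12 alone, where 1 control stands against 3 Cre-positive libraries, mean deviations with Cre less those without were 0.117 for hypoxia, 0.169 for rods, -0.479 for cell cycle and -0.327 for muscle.

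**Figure D2:**
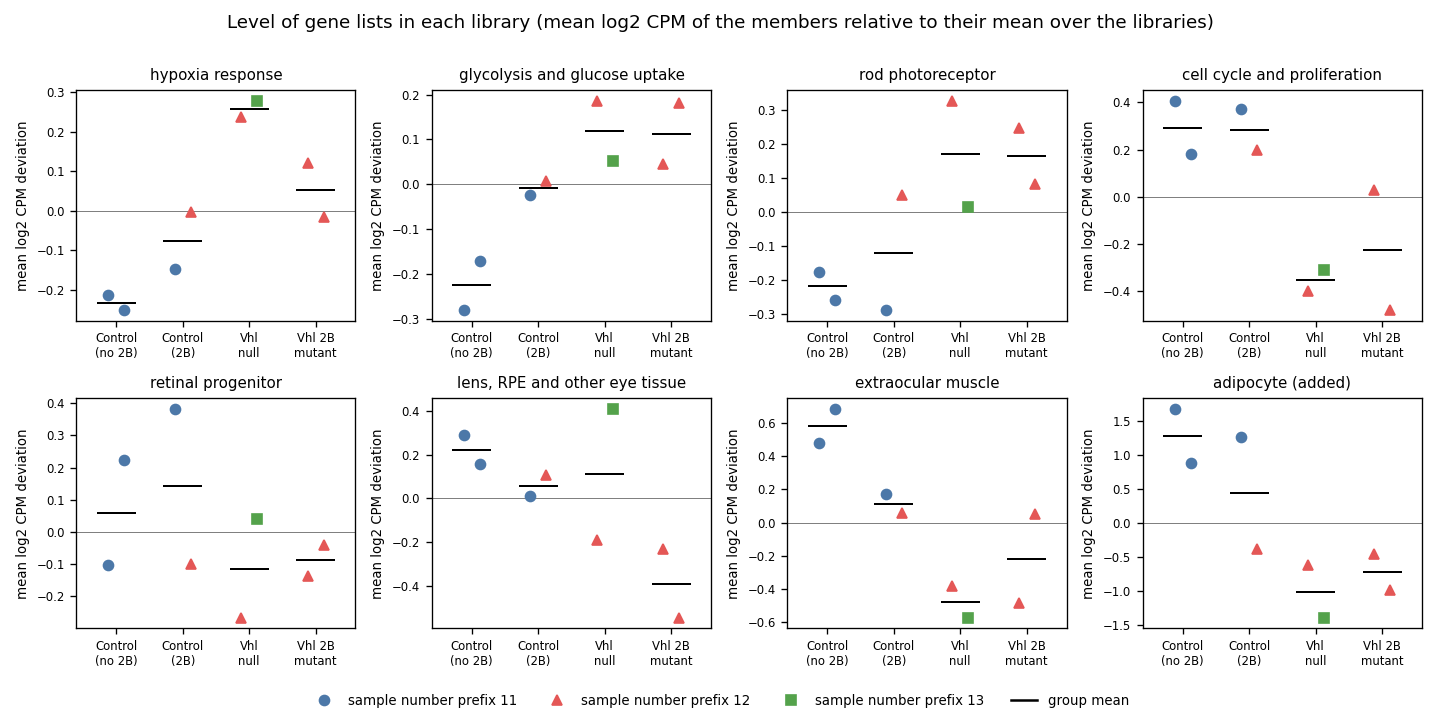
Level of 8 gene lists in each of the 8 libraries by genotype (horizontal axis), as the mean log2 CPM of the members relative to their mean over the libraries (vertical axis), with symbols for the sample number prefix and a black line at the group mean. For hypoxia response the null libraries lie at 0.236 and 0.278, above the other 6, while for rods, progenitors and adipocytes replicate 2 of the control with the 2B allele lies near the Cre-positive libraries.

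Over all genes edgeR called 0 in the pooled comparison, with 3015 at an unadjusted p under 0.05, DESeq2 called 220 (83 up, 137 down) and limma-voom 0. The unadjusted count was 494 without the libraries of prefix 11, 1626 or 1667 without either control lacking the 2B allele, and 5337 without Vhl null replicate 2. On simulated counts for this comparison, which held no differences by prefix, edgeR recovered 48% of genes changed 2-fold and 93% of those changed 4-fold. Without Vhl null replicate 2, the library with prefix 13 and with the highest shares of crystallin (30.9%) and haemoglobin counts, edgeR called 873 genes, 367 up and 506 down. All 3 Cre-positive libraries left then have prefix 12 and 3 of the 4 Cre-negative ones prefix 11, so these genes cannot be assigned to Cre rather than to the prefix. Of the hypoxia list 8 rose and 1 fell (Cox4i2, -0.89), and among those that rose were Vegfa (0.77 ± 0.19 SE, adjusted p = 0.0471) and Stc2 (1.35 ± 0.32 SE, adjusted p = 0.0434), and so did the phosphofructokinase Pfkp (1.13 ± 0.20 SE, adjusted p = 0.0285). Of the list of lens, RPE and other eye tissue 5 genes fell: Bfsp2, Crybb1, Crybb3, Krt12 and Pmel. Of the microglial list 4 fell, with the complement genes C1qa, C1qb and C1qc at -0.74, -0.79 and -0.72, and 6 muscle genes fell. Without replicate 2 of the control with the 2B allele 21 genes were called.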

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

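Among the tests in this part, those of the sample number prefix, of tissue carry-over, of a label swap, of the stage of development and of the lens share in the split by prefix were chosen after the result was seen. Among 88 gene or list levels checked in groups of 4 libraries, 1 library stood apart in 5, and chance gives about 1 in 20 groups. Among the Cre-positive libraries, Vhl null replicate 2 stood apart with 110.5 CPM of Vegfa where the others had 147.1 to 150.2 CPM, with 24.28 CPM of Hes1 (others 20.27 to 20.6), with 88.94 CPM of Egln1 (others 56.04 to 60.48) and with a bipolar cell list level of -0.335 (others 0.208 to 0.255). Among the Cre-negative libraries, replicate 2 of the control with the 2B allele had 24.22 CPM of Egln3 where the others had 11.35 to 13.23 CPM.

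Between the Vhl null and the 2B mutant, 11 lists had Cre effects called different by camera with the preset correlation, in a test of the difference itself. With an estimated correlation or with fry (directional or mixed), 0 of the 30 lists were called. The median difference, 2B mutant less null, was below 0 for glycolysis (-0.18), hypoxia response (-0.37), the Notch pathway (-0.24), vascular basement membrane (-0.24), microglia (-0.36), lens (-0.49), blood (-1.28) and immediate early genes (-0.42). It was above 0 for endothelial genes (0.38), muscle (0.67) and mitochondrially encoded transcripts (1.12). The estimated-correlation adjusted p was 0.486 for hypoxia and 0.696 for the other 10. Calls other than those of hypoxia and muscle ended when single libraries were left out. Without Vhl null replicate 2 the medians were -0.05 for Notch, 0.04 for basement membrane, 0.09 for microglia, -0.03 for lens, -0.07 for blood and -0.13 for immediate early genes. Without mutant replicate 1 they were -0.0035 for mitochondrially encoded transcripts (adjusted p = 0.549), 0.15 for endothelial genes (adjusted p = 0.237) and -0.18 for glycolysis (adjusted p = 0.0827). The muscle median was 0.28 without mutant replicate 2.

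The hypoxia list was higher in the Vhl null. Sex of the animals and the mean lens share of the library were nearly balanced between these groups. Each group held 1 library with Y-linked counts. Crystallins took 25.2 ± 0.356% of counts in the control and 26.1 ± 6.90% in the null. This balance argues against either as the whole source, and it means that a covariate could hardly move the estimate. The median of 0.44 was 0.39 with Xist and 0.41 with the crystallin percent as a covariate, with 39 and 40 of 47 members above 0. The list stayed called with either at the preset correlation (adjusted p = 3.46e-11 and 3.67e-11), and at an estimated one it was not called with them (0.412 and 0.542) or without (0.171). The sample number prefix stays open: with it the median was 0.29 (64.6% left, adjusted p = 0.000756; adjusted p = 0.818 with an estimated correlation), and the estimate then rests on the 1 Cre-negative library of prefix 12. Loss of Vhl may be the source of the shift, as may whatever the prefix stands for, and an effect of Cre itself was not tested.

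The muscle list was lower in the Cre-positive libraries. Unequal carry-over of tissue from outside the retina is a candidate explanation, since 10 of 13 adipocyte markers were lower there too (median -1.88). With an estimated correlation camera called this added list in the pooled comparison and 0 of the 30 fixed ones (adjusted p = 0.0465 over the 2 added lists, and 0.0244 with fry). The list was chosen after its genes were seen. Its mean deviation with Cre less that without was -1.72 over all libraries but -0.303 within prefix 12, and the prefix 12 control with the 2B allele lay 1.64 below its prefix 11 replicate. Ucp1, of brown fat, had 43.6, 20.4, 56.8 and 7.08 CPM without Cre and 0.0768 to 0.470 CPM with it, and Adipoq had 10.5, 7.07, 9.34 and 0.822 CPM without Cre and at most 0.154 CPM with it. The prefix is another candidate, since with it the muscle median of -0.68 was -0.22 (31.7% left, adjusted p = 0.00325; adjusted p = 0.772 with an estimated correlation). A biological effect of Vhl loss on muscle or fat beside the eye was not tested and stays open.

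Chance cannot be excluded for the lists of the pooled comparison: 13 of the 35 splits into 4 and 4 libraries gave at least the 10 called. The splits other than that by Cre gave a median of 9 lists, and the highest of them gave 15. The number of lists called with the preset correlation thus hardly sets the split by Cre apart. For genes called by edgeR the count of splits decides nothing, since all 35 reach the real count of 0 by construction, and the highest other gave 2229. At an unadjusted p under 0.05, 3 of 35 splits gave as many as its 3015 genes (DESeq2 called 220 and limma-voom 0), a count that was 494 without the libraries of prefix 11. The split with 2229 genes sets the 4 libraries of prefix 12 against the others, which points to a structure of the samples that follows the prefix. With Cre in that model 298 genes passed the threshold, and Cre with the split as a term had 0 by edgeR.

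For that split by prefix, a swap of labels between replicate 2 of the control with the 2B allele and Vhl null replicate 2 is argued against, since the latter had 20.05 CPM of Vhl where the lowest control had 39.2. A later stage of retinal development in the libraries of prefix 12 may explain part of it, as 3 of 3 lists went that way (rods higher, progenitors and cell cycle lower). With an estimated correlation these calls were lost (adjusted p = 0.744, 0.744 and 0.931). The cell cycle list is no separate sign of such a stage, since its level split the libraries by Cre. Replicate 2 of the control with the 2B allele, of prefix 12, had a level of 0.197, and the other controls had 0.18 to 0.406. Vhl null replicate 2, outside prefix 12, had -0.31. The lens share cannot be told apart from the split: with the crystallin percent as a covariate 12 genes passed the threshold in place of 2229, and the median size of the change of the 2229 was 0.61 (median SE 0.204) where it had been 0.70 (median SE 0.162), so the calls ended more through the wider error. With the prefix as a term the rod median between Cre groups was 0.21 (50.7% left, adjusted p = 0.0866). The cell cycle median was then -0.50 (86.1% left, adjusted p = 3.75e-06). For both, the adjusted p was 0.772 with an estimated correlation. Both medians rest on 1 Cre-negative library, so this term cannot tell either shift apart from the prefix.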

How the results depend on the processing

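The crystallin covariate, the removal of abundant transcripts, the refits without the 3 libraries with prefix 11, the unadjusted overlap and the list refits with the prefix or Xist were chosen after the data were seen. Of 738 refits of named genes, 704 kept direction and side of the threshold, 17 passed it newly and 17 turned. The genes were those named beforehand other than Vhl, with Adm, Stc2, Egln1, Mylpf, Tyms and Slc24a1 added after their values were seen. None passed in a main fit, so keeping the side only meant staying uncalled. The setting of a 1.5-fold change reuses the main fit and cannot turn a gene. Of 871 refits of called lists, 608 kept their call, 235 lost it and 28 turned. The main gene counts were all 0, so a gene count could be kept only by staying at 0, which is no measure of stability. Of 123 gene counts 80 did so, and of 93 list counts 70 stayed within 1.5 times. The direction of Vhl held in all 41 refits. Where no other reason is given, the cause was not tested. What depth limits was not tested by varying it. With no low-count filter, 36197 genes were fitted, the prior degrees of freedom went from 6.54 to 87.8 in the pooled fit and became unbounded in the 4-group fit, and edgeR called 695 genes in the null comparison, 157 in the 2B mutant, 57 between mutant and null, 302 between controls, 63 in the difference of Cre effects and 178 in the pooled comparison, 23 of them shared by the main comparisons.

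DESeq2 called 100, 35, 23, 21, 2 and 220 genes in the same order, 4 shared. With the prefix term 3 genes were called in the null, 4 in the mutant, 1 between controls and 33 in the pooled comparison, 2 shared, and lists numbered 9 between controls and 7 in the difference. With it Epas1 (-0.64), Dll4 (-0.61) and Hey1 (-0.14) turned in the null, Slc2a1 (-0.23), Egln3 (-0.32), progenitors (0.017) and mitochondrial respiration (0.0094) in the mutant, bipolar cells (-0.0018) and immediate early genes (0.0014) between mutant and null, basement membrane (0.20), microglia (0.13), lens (0.026) and immediate early genes (0.11) in the difference, and mitochondrial respiration (0.025) in the pooled comparison.

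With Xist as covariate 2 genes were called in the mutant and 2 in the difference, and Dll4 in the null (-0.012) and Slc2a1 in the mutant (-0.10) turned. With only the libraries compared, 14 genes were called in the mutant and 25 between controls, and this setting has no value for the difference and the pooled comparison, which use all 8 libraries. RLE size factors gave 1 gene (Gm8113) in the difference. With the crystallin covariate 1 gene was called between controls, 6 lists in the mutant and 3 between mutant and null, and Dll4 in the null (-0.041), blood in the mutant (0.070), bipolar cells (-0.095), microglia (0.061) and immediate early genes (0.058) between mutant and null, and basement membrane (0.13) and microglia (0.18) in the difference turned. Without the libraries of prefix 11, 1 gene was called in the pooled comparison, and Slc2a1 (-0.23), Egln3 (-0.32), progenitors (0.013) and mitochondrial respiration (0.0061) in the mutant and progenitors (0.052) and mitochondrial respiration (0.096) in the pooled comparison turned. For the mutant, the prefix term and the refits without prefix 11 or without replicate 1 of its control are not separate checks. Each in effect sets the mutants against replicate 2 of that control. At an unadjusted p under 0.05 in both, 430 genes were shared. With an estimated correlation 0 of the 30 fixed lists were called in each of the 6 comparisons, and with fry's directional test 0 in 5 and 2 in the pooled comparison. Fry's mixed test, which ignores direction, called 8 in the null, 16 in the pooled comparison and 0 in the others. Of the added lists, that of adipocytes was called in the pooled comparison with both (adjusted p = 0.0465 and 0.0244, over the 2 added lists).

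The replicate block gave 13 genes in the mutant, 1 between mutant and null, 2 between controls, 5 in the difference and 5 in the pooled comparison, but deviations of equally numbered replicates correlated between groups at -0.146 to 0.253, so the numbers do not pair the libraries and the block removes no known effect.

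Leaving out each library in turn, where a lone library left in a group is assumed to vary like the other groups, edgeR called 0 to 5 genes in the null, 0 to 10 in the mutant, 0 to 79 between mutant and null (79 without null replicate 1), 0 to 2 between controls, 0 to 4 in the difference and 0 to 873 in the pooled comparison (873 without null replicate 2), with 0 to 3 shared. Lists called ranged from 7 to 11, 8 to 14, 5 to 14, 5 to 10, 5 to 12 and 9 to 12. Values that turned ranged from -0.085 to 0.55 for Epas1 and -0.28 to 0.29 for Dll4 in the null. In the mutant they ranged from -0.23 to 0.33 for Slc2a1, -0.32 to 0.73 for Egln3, -0.39 to 0.021 for Pdgfrb, -0.51 to 0.016 for progenitors, -0.28 to 0.0089 for mitochondrial respiration and -0.23 to 1.31 for mitochondrially encoded transcripts. Between mutant and null they ranged from -0.0017 to 0.63 for bipolar cells, -0.090 to 0.39 for muscle and -0.67 to 0.016 for immediate early genes. In the difference they ranged from -0.64 to 0.086 for microglia, -0.57 to 0.035 for basement membrane and -0.0035 to 1.68 for mitochondrially encoded transcripts.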

Other observations

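The tests of the stretches around Psmb5 and Abhd14a were chosen after the result was seen, as were all genes named in this part. Abca1, which exports cholesterol from cells, was at 76.4 ± 2.75 CPM in the Vhl null and 34.8 ± 2.67 CPM in its control (log2 fold change 1.13 ± 0.20 SE, adjusted p = 0.131 by edgeR), and at 57.9 ± 11.6 CPM in the 2B mutant and 43.8 ± 1.45 CPM in its own control. Rsad2, an interferon-induced antiviral gene, was at 4.76 and 10.3 CPM in the null libraries and at 1.81 to 3.22 CPM in the other 6.

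Several genes stood apart in the 2B mutant. The zinc finger gene Zfp949 (chromosome 9, 88548020 to 88571061) was at 63.6 and 63.1 CPM there and at 10.3 to 33.2 CPM in the other 6 libraries (2.39 ± 0.31 SE against its control, adjusted p = 0.133). Abhd14a, a hydrolase gene with an exon that overlaps Abhd14b on the other strand, was at 7.98 and 9.47 CPM against 19.9 to 31.0 CPM (-1.58 ± 0.21 SE, adjusted p = 0.133). The proteasome subunit gene Psmb5 was at 44.6 and 44.4 CPM against 69.1 to 83.1 CPM (-0.86 ± 0.18 SE, adjusted p = 0.725). Rpl29, of the large ribosomal subunit, was at 171 and 76.3 CPM against 248 to 465 CPM. Gm8113 was at 0.0877 and 0 CPM in the 2B mutant and 0.238 and 0 CPM in the control without the 2B allele, while the other 4 libraries had 2.02 to 3.86 CPM (adjusted p = 0.0778 for the difference between Cre effects).

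DNA inherited along with the 2B allele around Vhl could change genes near it. Of the genes within 10 Mb of Vhl, 1.26% had an unadjusted p under 0.05 between 2B mutant and Vhl null. Windows of that size elsewhere had a median of 3.24% and a 95th percentile of 6.54%, so the share near Vhl was not raised. Over all genes that comparison had 673 such genes where chance gives 996. With no excess to explain, it cannot decide whether such DNA acts. Between the controls the share was 12.6%, with a median of 10.6% and a 95th percentile of 16.1%, which leaves it open. A shared stretch of chromosome 14 around Psmb5, or of chromosome 9 around Abhd14a, might carry the genes lower in the 2B mutant. With the genes that drew attention left out, 4.20% and 5.43% of the genes within 10 Mb of them had an unadjusted p under 0.05, below the 95th percentiles of 6.45% and 6.31%, and neither stretch is shown or excluded by these values.

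Epithelial transcripts varied as well. Krt5, a keratin of basal epithelium, was at 1137 CPM in replicate 2 of the control with the 2B allele and at 297 to 492 CPM in the other 7 libraries. The added corneal and skin epithelium list was lower in the 2B mutant than in its control (median -0.73, 11 of 12 below 0, adjusted p = 1.07e-05; adjusted p = 0.205 with an estimated correlation). DESeq2 called the Y-linked genes Kdm5d, Eif2s3y and Ddx3y in the 2B mutant against its control and between the controls, which rests on the sex of single samples. Eif2s3y was at 85.6 CPM in mutant replicate 2, 72.2 CPM in replicate 1 of the control without the 2B allele and 55.5 CPM in Vhl null replicate 2, and had no counts in the other 5 libraries.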
